A study of Mus musculus with 11 samples.

How the data were processed

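mRNA libraries of retina from mice at postnatal day 21 were compared between 5 wild-type and 6 Nrl knock-out samples. Each sample's genotype and replicate number came from its title in the labels. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, of which a part can be technical. Per the labels' protocols, barcoded TruSeq libraries were pooled in equal amounts and sequenced as stranded single-end reads of 50 bases. The labels name polyA RNA in one place and removal of ribosomal RNA in another, so the way mRNA was selected is not settled here.

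The authors deposited 1 table of 23284 genes, named by symbol. Its 11 library columns hold a signal that the authors made by dividing read counts per gene by 1 size factor per library; it is scaled neither to a fixed total nor to gene length. Further deposited columns hold the authors' mean signal over the libraries, their log2 fold change and their adjusted p-value, per the file headers; a column of medians was not used here. The submitters' processing notes name TopHat2 2.1.1, HTSeq 0.6.0, DESeq without a version and the mouse build mm9; they give no role or order for these, and the gene annotation and strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes and of genes with near-identical copies are therefore uncertain. The 4 haemoglobin genes on the lists are listed at 0 in all 11 libraries, and Eno1 and Gapdh, which have many processed copies, have few reads.

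Every value of a library was a whole multiple of 1 step to within 1e-06 of a read, for 100% of values in each of the 11 libraries, and the step equalled 1 over the median-ratio size factor. Whole reads per gene were recovered from this. They totalled between 14907613 and 20685840 per library, and 4192 genes had no read in any library. A count of 0 allows up to 3 reads, which is 2.61 to 3.59 normalized counts depending on the library. Counting intervals are at the 95% level and cover counting error only, since the reads carry no molecular identifiers.

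The design written beforehand named edgeR's test for raw counts and limma for normalized values; the table holds normalized values, so limma 3.58.1 in R 4.3.3 gave the main result. Genes with a normalized count of at least 10 in at least 5 libraries were tested, which left 14584. All limma and edgeR tests are two-sided. limma was fitted with a mean-variance trend and robust moderation to log2(normalized count + 1), with genotype as the only term and all 11 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and at least 2-fold where the absolute log2 fold change was also at least 1. Fold changes are on the log2(normalized count + 1) scale, which understates changes of low genes. The same step run on simulated counts with 200 changed genes recovered 56% of genes changed 1.25-fold, 82% of those changed 1.5-fold, 97.9% of those changed 2-fold and 100% of those changed 4-fold, and 3.51% of its calls were false, over 14317 genes in a simulated knock-out against wild-type comparison. The simulation changed far fewer genes than were called in the data, equally up and down, so these percentages need not hold for the real comparison.

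28 gene lists with 428 entries were fixed before the data were examined, together with the processing alternatives and the rule for named genes. The rule takes Nrl; the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 normalized counts in the higher group, groups that do not overlap and a symbol that is not a predicted-gene name; from each list the 3 called members with the largest change and the member with the highest level, or the highest pair where none was called; all members of the rod phototransduction, cone phototransduction and photoreceptor transcription factor lists; and both genes of each of 11 rod and cone paralogue pairs. 15 tested genes stand on more than 1 list. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 28 lists, and again with an estimated correlation. fry was run beside it, which asks whether a list's genes move, on balance, one way, and does not compare them with other genes. Paralogue ratios were taken per library as log2 of CPM + 1 (CPM, reads scaled to a library total of 1e+06) of the cone gene minus that of the rod gene. Ratios and each list's share of the library's reads were compared by exact two-sided permutation tests over the 462 ways to split the libraries, where the smallest possible p is 0.00216, adjusted over the 11 pairs or 28 lists.

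Alternatives were DESeq2 1.42.0, limma-voom and edgeR 4.0.16 on the recovered reads, other scalings of the libraries, other filters and pseudocounts, the replicate number as a block, stricter thresholds, and leaving out each library in turn. edgeR's quasi-likelihood test with TMM scaling, limma with TMM, upper-quartile or library-total scaling, and the fit without both wild-type replicate 1 and knock-out replicate 2 were added after seeing the data. On the recovered reads edgeR with TMM called 6760 genes, limma-voom 6756 and DESeq2 6937, against 6752 by limma on the normalized values. In the simulation 4.02% of edgeR's calls, 4.09% of limma-voom's and 6.63% of DESeq2's were false.

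Gene neighbours were taken from a mouse gene table of another build than mm9, used only for which genes lie next to each other, so no coordinates are given; 99.4% of tested genes were matched to it by symbol or synonym. The list genes Samd11, Lamp5 and Chmp4a are not named in the table and were not analysed. Results of some single genes, and of 1 gene pair and some tests that rest on them, are not reported here.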

Results

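The retinal transcriptome of mice lacking Nrl was compared with that of wild-type mice at postnatal day 21. Nrl encodes a leucine zipper transcription factor of rod photoreceptors. 5 wild-type and 6 Nrl knock-out mRNA libraries were measured as size-factor normalized counts per gene. The wild-type libraries held between 16126210 and 20685840 reads in genes and the knock-out libraries between 14907613 and 19877314. The 10 most abundant genes together took 10.2% ± 0.6 (SD, n = 5) of wild-type reads and 3.94% ± 0.17 (SD, n = 6) of knock-out reads. The first principal component of the libraries held 76.7% of the variance and separated the genotypes. The second held 7.34%, and on it wild-type replicate 1 (26.5) and knock-out replicate 2 (19.0), the shallowest library of each genotype, lay farthest to one side. Spearman correlations between libraries were 0.992 to 0.998 within a genotype and 0.962 to 0.969 between genotypes.

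Nrl itself stood at 37017 ± 1947 normalized counts in wild-type retina (SD, n = 5) and at 51.7 ± 5.1 in knock-out retina (SD, n = 6), so that it fell by 9.46 on the log2 scale (SE 0.06) and the libraries matched their labels. Counts per gene do not show which exons the remaining Nrl reads cover. In knock-out retina all 12 genes of the rod light response fell, some of them almost to 0, those of the cone light response rose about 10-fold in their share of reads, and 16 of 17 reactive gliosis genes rose. All genes of the microglia and interferon lists were also called higher, although as lists these did not pass with an estimated correlation between genes (adjusted p = 0.117 and 0.138). In all, 6752 of 14584 tested genes were called (limma, adjusted p under 0.05), 3448 higher and 3304 lower in the knock-out. Of these, 1133 differed at least 2-fold, 754 higher and 379 lower, while 2880 differed by less than 0.32 on the log2 scale. The groups did not overlap for 4506 genes, where chance gives 0.433% of genes. The balance of directions depended on the scaling. With libraries scaled to their total count, 77.6% of calls were higher in edgeR (5883 higher, 1703 lower) and 77.4% in limma (5861 and 1711), against 51.1% with the authors' size factors, because the median log2 fold change of all tested genes moved from -0.01 to 0.13. The authors' deposited table held 6917 genes with an adjusted p under 0.05, 3574 higher and 3343 lower, and 6556 of them were also called here, all in the same direction.

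All 12 tested rod phototransduction genes fell, with a median log2 fold change of -4.86 (camera adjusted p = 2.25e-20). Gnat1, the rod transducin alpha subunit, fell from 321354 ± 21513 to 210.4 ± 15.8 normalized counts, and Cnga1, a subunit of the rod cyclic nucleotide-gated channel, from 18675 ± 822 to 10.04 ± 2.57. The rod exchanger gene Slc24a1 (-8.02), Cngb1 (-5.38), the phosphodiesterase subunits Pde6b (-5.13) and Pde6a (-3.80), Gnb1 (-4.59) and Guca1b (-3.40) fell by less. The smallest falls were those of Pde6g (-2.10), Gngt1 (-1.13) and Sag, rod arrestin (-0.64, SE 0.07). Of 10 other rod-enriched genes 9 fell (median -3.97, adjusted p = 1.91e-12), among them Nr2e3 (-10.76), the potassium channel gene Kcnj14 (-7.98), Susd3 (-6.69) and Reep6 (-5.74); Elfn1 stood at 2252 ± 120 and 2262 ± 87. The rod phototransduction genes together took 8.79% ± 0.51 of reads in wild type and 0.561% ± 0.055 in the knock-out.

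All 10 cone phototransduction genes rose (median log2 fold change 3.24, adjusted p = 1.66e-15), and their share of reads went from 0.167% ± 0.008 to 1.66% ± 0.11. The cone channel gene Cngb3 (3.96, SE 0.06), the short-wavelength opsin gene Opn1sw (3.77, SE 0.07) and the cone phosphodiesterase gene Pde6c (3.63, SE 0.05) rose most. Opn1sw went from 8151 ± 699 to 111774 ± 11516 normalized counts, while the middle-wavelength opsin gene Opn1mw rose least of the 10, from 3007 ± 147 to 6614 ± 748 (1.13, SE 0.06). Gngt2 (3.47), Cnga3 (3.32), Gnat2 (3.17), Pde6h (2.78), Gnb3 (2.72) and Arr3, cone arrestin (2.59), lay between. Of 8 other cone-enriched genes 7 rose (median 2.73, adjusted p = 3.73e-10), led by Otop3 (3.63), Ccdc136 (2.97) and Fam19a3 (2.94). Thrb, which encodes a thyroid hormone receptor of cones, was not called (2379 ± 47 and 2486 ± 46, adjusted p = 0.15), but was called with libraries scaled to their total (0.20, adjusted p = 6.8e-05 in limma). Both rod lists and both cone lists also passed with an estimated correlation between genes, the largest adjusted p being 0.0163 for cone phototransduction.

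Rods and cones largely use different members of the same gene families, and the ratio of such members was taken within each library. In all 10 pairs described here the cone member gained on the rod member, each with an exact permutation p of 0.00216, the smallest the 462 splits can give. The log2 ratio of Gnat2 to Gnat1 went from -6.67 ± 0.07 (SD, n = 5) to 6.95 ± 0.14 (SD, n = 6) and that of Cnga3 to Cnga1 from -5.50 ± 0.10 to 7.19 ± 0.13. The size of the Cnga3 to Cnga1 difference (12.69) depends on the CPM added before the log, since Cnga1 had 63 reads over the knock-out libraries. It was 13.98 with 0.1 and 10.65 with 5 in place of 1. The differences in the log2 ratio were 9.22 for Cngb3 to Cngb1, 9.17 for Slc24a2 to Slc24a1, 8.74 for Pde6c to Pde6b, 7.42 for Pde6c to Pde6a, 7.30 for Gnb3 to Gnb1, 4.88 for Pde6h to Pde6g and 4.59 for Gngt2 to Gngt1. The pair of arrestins moved least, by 3.22, and its ratio of Arr3 to Sag was still below 0 in the knock-out (-1.15 ± 0.35). Sag stood at 60459 ± 7218 normalized counts in the knock-out, so whether it is particular to rods is uncertain.

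**Figure D1:**
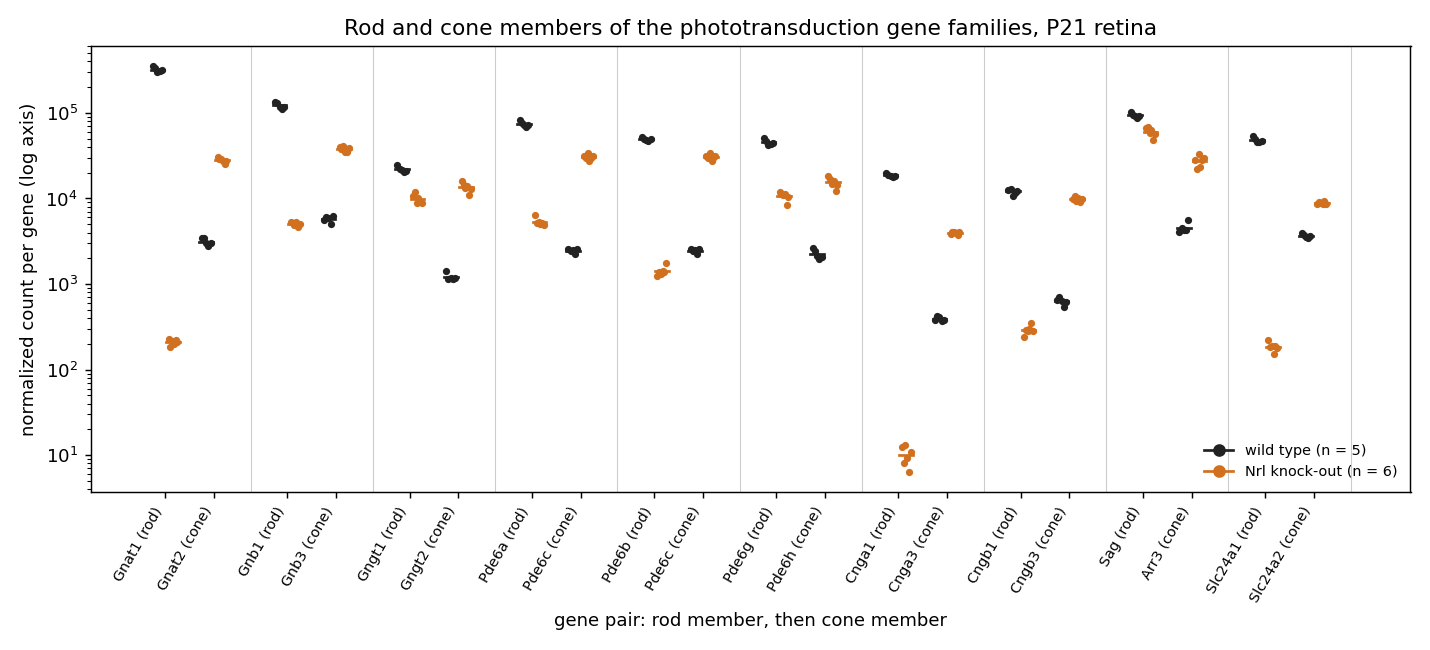
Normalized counts (log axis) of the rod and cone members of 10 gene pairs in 5 wild-type (black) and 6 Nrl knock-out (orange) retina libraries; points are libraries and bars are group means. The rod member is above the cone member in every wild-type library, and in the knock-out libraries the cone member is above the rod member in every pair except Arr3 and Sag.

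Among 18 photoreceptor transcription factors, 8 rose and 7 fell, or 8 and 8 adjusted over the list alone, where 46.3% of all tested genes were called. As a list they were not shifted in one direction against other genes (median log2 fold change -0.02, mean -0.64, camera adjusted p = 0.954). A test for a shift in one direction cannot weigh a list whose members moved both ways. The median was 0.12 with libraries scaled to their total. Nr2e3, a nuclear receptor of rods, fell from 9696 ± 837 to 4.87 ± 1.97 normalized counts. Esrrb (-4.36) and Mef2c (-3.57) also fell steeply, and Samd7 (-1.10) and Rorb (-0.79) less so. Rxrg (2.76, SE 0.07) and Sall3 (2.70, SE 0.07), both known from cones, rose, as did Prdm1 (2.23, SE 0.05), which went from 369 ± 6 to 1737 ± 130. Otx2 (0.63), Neurod1 (0.53), Nr1d1 (0.34) and Rora (0.24) rose by less than 2-fold. Mef2d was called at 0.16, and the call ended without wild-type replicate 2 (0.14, adjusted p = 0.068) or replicate 3 (0.15, adjusted p = 0.0504), and without both wild-type replicate 1 and knock-out replicate 2 (0.14, adjusted p = 0.054). Crx, the photoreceptor homeobox gene, fell by 0.20 (24941 ± 604 to 21710 ± 937) and Casz1 by 0.20, and both calls ended with libraries scaled to their total (-0.06 and -0.06 in limma). Tbx2 (-0.10) and Pias3 (-0.14, adjusted p = 0.063) were not called; Pias3 was called without wild-type replicate 1 (-0.16) and without knock-out replicate 3 (-0.17) or 6 (-0.17).

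**Figure D2:**
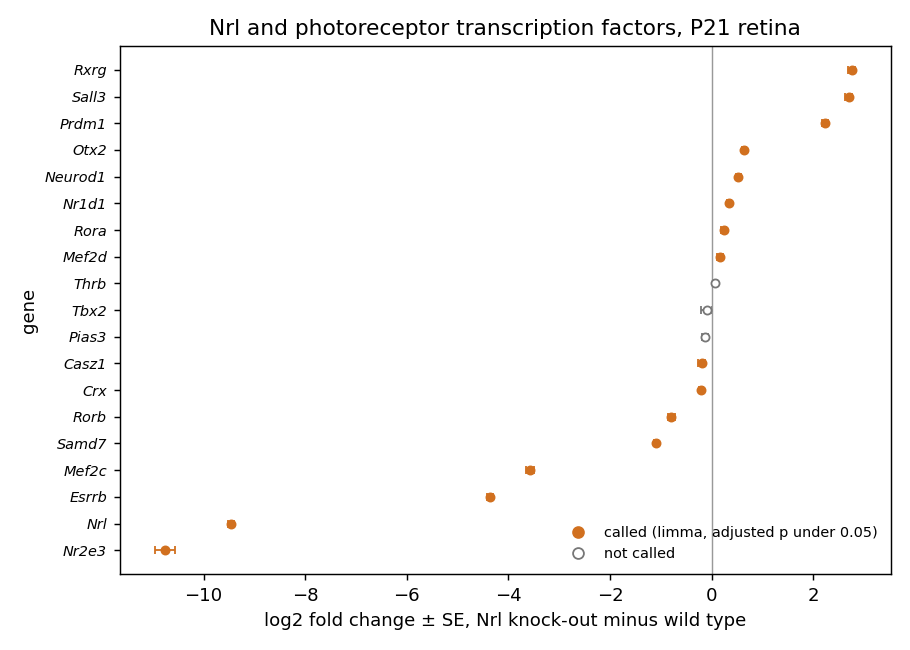
Log2 fold changes with their standard errors (limma, knock-out minus wild type, 5 against 6 libraries) of Nrl and 18 photoreceptor transcription factors; filled points were called and open points were not. Nr2e3 and Nrl lie at -10.76 and -9.46 and Rxrg and Sall3 at 2.76 and 2.70.

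Of 29 photoreceptor genes shared by rods and cones 22 fell and 6 rose (median log2 fold change -1.01, camera adjusted p = 2.47e-12; adjusted p = 0.138 with an estimated correlation). The guanylate cyclase gene Gucy2f (-6.09), the fascin gene Fscn2 (-5.10) and the disc rim gene Rom1 (-2.39) fell most. The falls of Gucy2f and Fscn2 were near those of Cngb1 (-5.38) and Pde6b (-5.13) of the rod list, so whether cones share these genes is uncertain. Rbp3, which encodes the interphotoreceptor retinoid-binding protein, stood at 179634 ± 16699.6 and 204236 ± 9762 normalized counts (0.19, SE 0.05) and was the most abundant gene of every knock-out library. Of 20 photoreceptor synapse genes 10 fell and 6 rose (median -0.15, or -0.01 with libraries scaled to their total, adjusted p = 0.456), with Cabp4 at -1.21 and Elfn2 and Lrit3 at 1.06 and 0.96. The vesicular glutamate transporter gene Slc17a7 fell by 0.28. Against the sign of the median, the synapse genes' share of reads rose from 0.997% ± 0.012 to 1.10% ± 0.02 (exact permutation p = 0.00216, adjusted 0.00379), a call that ended with the 10 most abundant genes left out of the total (adjusted p = 0.0854). Of 24 photoreceptor cilium genes 12 fell and 6 rose, or 12 and 7 adjusted over the list alone (median -0.25). Rp1 fell by 1.99 and Cdh23 went from 18.2 ± 6.7 to 5.73 ± 1.94, while Pcdh15 rose from 7784 ± 697 to 26844 ± 3650 (1.78, SE 0.09). The cilium list missed the threshold (camera adjusted p = 0.0696). It passed without wild-type replicate 1 (0.038), without knock-out replicate 3 (0.046) and in DESeq2 (0.036). It also passed without the low-count filter (0.039) and with libraries scaled to their total (0.031). fry, which does not compare a list with other genes, gave an adjusted p of 3.8e-06. That does not set the cilium list apart. fry also passed bipolar cell (4.9e-05) and dorsoventral genes (9.2e-05), which camera did not, but not synapse (0.093) or horizontal cell genes (0.80).

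The ganglion, amacrine, bipolar and horizontal cells are neurons of the inner retina. Of 14 retinal ganglion cell genes 12 fell and none rose (median log2 fold change -0.35, camera adjusted p = 0.000464; 0.461 as adjusted p with an estimated correlation). Opn4, the melanopsin gene, fell from 135.77 ± 20.01 to 72.3 ± 11.1 (-0.90, SE 0.13), Ebf1 fell by 0.46, and Tubb3 and the neurofilament gene Nefl by 0.39 and 0.38. Of 15 amacrine cell genes 11 fell and none rose, or 14 and 0 adjusted over the list alone (median -0.31, adjusted p = 0.000133; adjusted p = 0.207 with an estimated correlation), among them Th (-0.71), Chat (-0.46) and Slc18a3 (-0.43). With libraries scaled to their total the ganglion and amacrine medians were -0.22 and -0.18, and in DESeq2 the lists missed the threshold (adjusted p = 0.0858 and 0.0542). Of 22 bipolar cell genes 9 rose and 2 fell, or 10 and 2 adjusted over the list alone, which was not past the threshold as a list (median 0.14, adjusted p = 0.0855). Cabp5, a calcium-binding protein of bipolar cells, rose from 1957 ± 59 to 6765 ± 349 (1.79, SE 0.04) and Car8 rose by 0.87 and Lrtm1 by 0.54. Prkca, the rod bipolar marker, fell from 9860 ± 471 to 6321 ± 579 (-0.65, SE 0.06). Of 7 horizontal cell genes, Sept4 (0.20) and Onecut2 (0.38) were called higher and Lhx1 (-0.45) lower (list median -0.17, adjusted p = 0.947). The Onecut2 call ended when any of wild-type replicates 1 to 4 or knock-out replicates 3 to 6 was left out, with values from 0.29 to 0.40, and without both wild-type replicate 1 and knock-out replicate 2 (0.34).

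Of 17 reactive gliosis genes 16 rose and 1 fell (median log2 fold change 1.90, camera adjusted p = 4.98e-13; 0.0163 as adjusted p with an estimated correlation). The acute-phase genes Serpina3n (125 ± 7 to 2039 ± 247 normalized counts; 4.01, SE 0.08), C4b (4.00, SE 0.07) and A2m (3.21, SE 0.09) rose most. The intermediate filament gene Gfap, a marker of glial reaction, rose from 703 ± 65 to 2473 ± 302, and Edn2, an endothelin made by stressed photoreceptors, fell from 138 ± 55 to 45.98 ± 12.01. C4b and Serpina3n belong to families with close copies, so reads may be split between them. Of 15 Müller glia genes 7 rose and 1 fell (median 0.27, adjusted p = 0.0203; adjusted p = 0.426 with an estimated correlation). Clu (1.17), Apoe (1.01) and Vim (0.80) rose, while Glul, the glutamine synthetase gene and the most abundant of the list, fell by 0.27.

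All 17 microglia and macrophage genes rose (median log2 fold change 2.25, camera adjusted p = 9.82e-13; adjusted p = 0.117 with an estimated correlation). The complement genes C1qc (89.4 ± 17.5 to 530 ± 97; 2.55, SE 0.13) and C1qa (2.45, SE 0.13) and Cd74, the invariant chain of MHC class II (2.43, SE 0.35), rose most, and the lysosomal protease gene Ctss was the most abundant in the knock-out (240.01 ± 33.49 to 1236 ± 239). The list took 0.00937% ± 0.00074 of wild-type reads and 0.0364% ± 0.0054 of knock-out reads (exact permutation p = 0.00216). All 15 interferon response and MHC class I genes rose as well (median 2.03, adjusted p = 3.45e-12; adjusted p = 0.138 with an estimated correlation), with Ifit1 at 2.72 (SE 0.18), Usp18 at 2.62 (SE 0.21) and H2-K1 at 2.43 (SE 0.06). Class I genes have close copies, which makes the value of each uncertain.

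Of 14 genes of the unfolded protein and integrated stress response 11 rose and none fell, or 12 and 1 adjusted over the list alone (median log2 fold change 0.45, camera adjusted p = 2.18e-05; adjusted p = 0.138 with an estimated correlation). Sdf2l1 (1.69), the endoplasmic reticulum chaperone gene Hspa5 (6170 ± 454 to 16608 ± 2527; 1.42, SE 0.09) and Xbp1 (1.27, SE 0.06) rose most, and Hsp90b1 rose by 0.46. Of 17 glycolysis genes 11 fell and 2 rose (median -0.28, or -0.15 with libraries scaled to their total, adjusted p = 0.0086; adjusted p = 0.461 with an estimated correlation, and 0.0569 in DESeq2), with Hk1 (-0.67), Pfkl (-0.65), Pfkp (-0.59) and Aldoa (-0.40) lower. Of 11 immediate early genes 6 rose and 1 fell, or 7 and 2 adjusted over the list alone (median 0.60, adjusted p = 0.0124; adjusted p = 0.147 with an estimated correlation, and 0.0666 with libraries scaled to their total). Egr1 (676 ± 173 to 2865 ± 705), Nr4a1 (1.17) and Btg2 (1.04) rose. Of 15 circadian clock genes 5 rose and 3 fell, or 7 and 3 adjusted over the list alone (median 0.14, adjusted p = 0.307), with Arntl at -0.69 and Tef and Nr1d2 at 0.47 and 0.43. Because camera looks for a shift in one direction, this does not exclude a clock difference in which genes move both ways. A difference in the time of dissection was not tested. Of 11 dorsoventral patterning genes 2 rose and 3 fell (median -0.07, or 0.06 with libraries scaled to their total; adjusted p = 0.456). Vax2, a ventral homeobox gene, fell from 520.0 ± 31.2 to 232.5 ± 9.6 (-1.16, SE 0.06), Cyp26a1 rose by 0.85, and Aldh1a1 stood at 1153 ± 125 and 1159 ± 111. Cyp26c1, with 35 reads in wild type and 80 in the knock-out over all libraries, was called at 0.84, and the call ended without wild-type replicate 3 (0.69) or 5 (0.62), without knock-out replicate 3 (0.85), 4 (0.82) or 5 (0.74), in DESeq2 (adjusted p = 0.088) and in edgeR with upper-quartile scaling (adjusted p = 0.051).

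Lists of tissues that dissection can bring along were also counted. Of 13 retinal pigment epithelium genes 2 were called higher and 1 lower, or 1 and 1 adjusted over the list alone (median 0.19, adjusted p = 0.946). The melanosome gene Pmel rose from 47.3 ± 28.7 to 147.0 ± 45.1 (1.74, SE 0.35) and Rrh fell by 0.30, while Ttr (0.39), the most abundant in the knock-out, was not called, although it was without knock-out replicate 5 (0.50, adjusted p = 0.029) and with libraries scaled to their total (0.53). The pigment gene Dct was called at 0.99 (SE 0.36), and its adjusted p was 0.058 in edgeR and between 0.068 and 0.096 without any one of wild-type replicates 2 to 5 or knock-out replicates 1, 2, 4 or 6. Of 12 endothelium and pericyte genes 3 rose and 1 fell, or 2 and 0 adjusted over the list alone (median -0.06 and mean 0.03, median 0.07 with libraries scaled to their total, adjusted p = 0.947), with Vwf at 1.11 and Rgs5 at 0.46. Kdr, the most abundant, was not called (0.07), but was with libraries scaled to their total (0.20). Pecam1 was called at -0.31, a call that ended without wild-type replicate 1 (-0.26) or 4 (-0.28), without knock-out replicate 3 (-0.25) or 6 (-0.25) and with libraries scaled to their total (-0.17). Only 2 of 16 lens genes passed the filter, Crybb3 (0.49) and Mip (0.38), and neither was called (adjusted p of the list = 0.636; Crybb3 was without both wild-type replicate 1 and knock-out replicate 2, at 0.79), but wild-type replicate 1 alone held 128 reads of the lens crystallin gene Cryaa, against 10 or fewer in the other wild-type libraries and 31 in knock-out replicate 5. Without wild-type replicate 1 the counts of called genes were 6741 and, at least 2-fold, 1144, and without it and knock-out replicate 2 they were 6527 and 1129. The single red blood cell gene that passed, Alas2 (-0.04, or 0.09 with libraries scaled to their total, adjusted p of the list = 0.954), and the 6 skeletal muscle genes that passed, such as Pvalb (-0.10) and Ckm (-0.24), were not called (adjusted p of the muscle list = 0.456). Of 29 genes next to Nrl on its chromosome 6 rose and 3 fell (median 0.08, adjusted p = 0.146), led by Cmtm5 (1.61), Irf9 (303 ± 33 to 729 ± 119) and Ipo4 (0.69). Dcaf11, the most abundant, was not called (0.07), but was without knock-out replicate 5 (0.10) and with libraries scaled to their total (0.20). Of 4 Y-linked genes Uty rose by 0.25 (median 0.18, adjusted p = 0.593) and Ddx3y was not called (-0.16), but was without knock-out replicate 5 (-0.22, adjusted p = 0.041).

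The largest changes lay partly outside the lists. Beside those of Nr2e3, Cnga1, Gnat1, Nrl, Slc24a1 and Kcnj14, the steepest falls were those of the histidine decarboxylase gene Hdc (386 ± 42 to 0.750 ± 1.023 normalized counts), Nipal1 and Sh2d1a (176.8 ± 12.5 to 0.769 ± 0.694). Nipal1 had 942 reads over the wild-type libraries and 1 over the knock-out libraries, a ratio of 1206 with a counting interval of 216 to 47690. The steepest rises were those of Ermap (7.56 ± 2.81 to 799 ± 45; 6.61, SE 0.16), Fabp7, a fatty acid-binding protein gene (18.3 ± 7.2 to 966 ± 69; 5.73, SE 0.20), Arid3c (5.66), Tc2n (5.54) and Poteg (5.11). They were followed by the interferon-induced chemokine gene Cxcl10 (1.82 ± 2.01 to 86.2 ± 53.2; 5.08, SE 0.50), Myocd (4.70), the integrin gene Itgax (4.70), Eya1 (69.4 ± 9.9 to 1602 ± 62; 4.52, SE 0.08) and Alx4 (4.51). Poteg, Itgax, Cxcl10 and Alx4 had between 7 and 11 reads over all wild-type libraries, so the size of their rise is less certain than that of Eya1 or Fabp7.

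**Figure D3:**
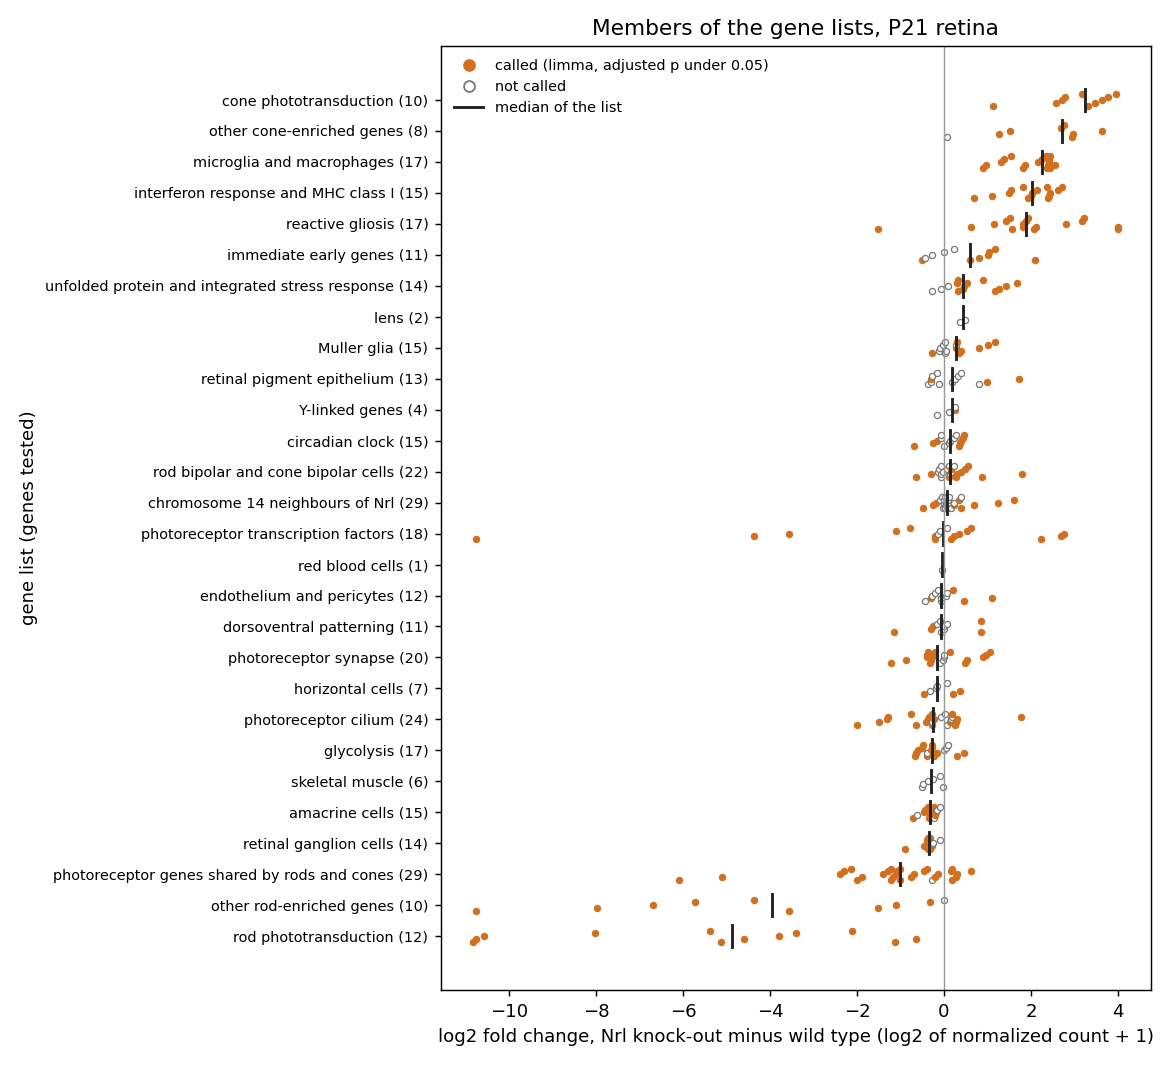
Log2 fold changes (limma, knock-out minus wild type, on log2 of normalized count + 1) of the tested members of 28 gene lists; filled orange points were called, open points were not, and black bars are list medians. The rod phototransduction list has its median at -4.86 and the cone phototransduction list at 3.24, with microglia, interferon and gliosis lists between 1.90 and 2.25.

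Of the 28 lists 14 were past the threshold with the preset correlation and 5 of them with an estimated one, namely both rod lists, both cone lists and reactive gliosis. With libraries scaled to their total, medians moved to -0.11 for cilium, 0.27 for bipolar cell, -0.03 for horizontal cell, 0.40 for Müller glia, 0.33 for pigment epithelium, -0.17 for muscle, 0.27 for clock, 0.21 for Nrl neighbour and 0.31 for Y-linked genes. Over all alternatives medians ran from 0.16 to 0.40 for Müller glia, 0.09 to 0.27 for bipolar cell, 0.05 to 0.33 for pigment epithelium and -0.36 to -0.10 for muscle genes. Against the sign of their medians, the shares of reads of horizontal cell genes (0.0400% to 0.0455%, exact permutation p = 0.00866, adjusted 0.0128) and endothelium genes (0.0429% to 0.0504%, exact permutation p = 0.00433, adjusted 0.00673) rose. Both calls ended with the 10 most abundant genes left out of the total (adjusted p = 0.105 and 0.0722). Over the 27 alternatives the horizontal cell median ran from -0.25 to 0.13 and the endothelium median from -0.10 to 0.14, so the sign of neither is settled. In 19 lists the counts of higher and lower genes adjusted over the list alone equalled those over all genes tested, and for the other 9 lists both are given above. Another list holds 5 of the other rod-enriched genes, 3 of the other cone-enriched genes, 5 of the genes shared by rods and cones, 11 of the transcription factors, 2 each of the synapse and cilium genes and 1 each of the dorsoventral and clock genes.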

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

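No test in this part was chosen after the results were seen: it follows a fixed rule, by which the highest or lowest library of a genotype stood apart from the rest by more than Dixon's 95% criterion. Of 360 groups of values 22 were marked in this way, where chance alone marks about 18. 7 of them fell in wild-type replicate 1 and 6 in knock-out replicate 5.

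Wild-type replicate 1 held 119.8 normalized counts of C1qc, against 76.7 to 87.3 in the other wild-type libraries. It was also highest in Chat (471, others 394 to 407), in Cp (4485, others 3988 to 4056) and in Gngt2 (1423, others 1153 to 1184), and lowest in Fam19a3 (1751, others 2346 to 2512). Its share of reads in bipolar cell genes was 0.227%, against 0.272% to 0.284%. Its share in lens genes was 0.00253%, against 0.000213% to 0.000396%. Wild-type replicate 5 was highest in Arr3 (5545, others 4043 to 4470) and in Cdh23 (30.0, others 13.6 to 16.4), and wild-type replicate 3 was lowest in Rxrg (134.9, others 165 to 177).

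Knock-out replicate 5 held 89893 normalized counts of Opn1sw, against 111244 to 121133 in the other knock-out libraries. It was also lowest in Slc17a7 (31322, others 34898 to 35674) and in Dcaf11 (2282, others 2568 to 2678), and its share of reads in photoreceptor genes shared by rods and cones was 3.26%, against 3.52% to 3.64%. It was highest in A2m (2400.2, others 1562 to 1798) and in Lrtm1 (11826, others 10420 to 10811). Knock-out replicate 2 was highest in the interferon-induced genes Ifit1 (786, others 355 to 504) and Usp18 (264, others 103 to 136). Knock-out replicate 1 was highest in Pde6a (6391, others 4913 to 5373) and lowest in its share of horizontal cell genes (0.0410%, others 0.0456% to 0.0476%). Knock-out replicate 3 held 2.61 normalized counts of Hdc, against 0 to 0.964. Knock-out replicate 4 held the only read of Nipal1 in its genotype (0.926 normalized counts).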

How the results depend on the processing

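The alternatives that leave out both wild-type replicate 1 and knock-out replicate 2, that run edgeR with TMM, or that rescale limma's input were chosen after seeing the data. The rod, cone, shared photoreceptor, gliosis, microglia, interferon, Müller glia and stress response lists kept their direction and stayed past the threshold with the preset correlation in all 27 alternatives run on lists, and so did the ratios of the gene pairs in theirs. With an estimated correlation the shared photoreceptor (adjusted p = 0.138), microglia (0.117), interferon (0.138), Müller glia (0.426) and stress response (0.138) lists did not pass. No gene taken by the rule for named genes changed direction while called in any alternative. Nor did any list fixed beforehand, its share of reads or a gene pair ratio. Genes named in the text outside that rule, such as Gfap and Edn2, were not part of this check. The same holds for the groups added after the main results, such as cholesterol synthesis, and for their genes outside the rule. Of the named genes' values under the alternatives 3697 stayed on their side of the threshold, 43 lost and 18 gained a call.

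Scaling to the library total gave 5883 higher and 1703 lower genes in edgeR and 5861 and 1711 in limma. Requiring a CPM of 10 in 5 libraries, which tests fewer genes, left 594 genes changed at least 2-fold, 350 higher and 244 lower. Testing against a 1.5-fold change in edgeR called 1403 genes, 921 higher and 482 lower, by its construction. An adjusted p under 0.01 called 5151. Without each library in turn between 6185 and 6741 genes were called, and between 1130 and 1155 at least 2-fold; all these fits test fewer libraries.

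The cilium list (main median -0.25) passed at a median of -0.24 in DESeq2, -0.11 with the library total in edgeR and -0.11 in limma, -0.25 without a low-count filter and -0.24 without both named libraries; its median was between -0.28 and -0.19 without each library in turn. In DESeq2 the amacrine (-0.31), ganglion cell (-0.35) and glycolysis (-0.29) lists missed the threshold. The immediate early list missed it with the library total (0.76 in edgeR and 0.73 in limma). With the 10 most abundant genes left out of the total, the differences in percent of reads for synapse (0.0259), horizontal cell (0.00264) and endothelium (0.00452) genes missed the threshold and those for ganglion cell (-0.0361) and dorsoventral (-0.00227) genes passed it. With all genes in the total the difference was -0.0226 for ganglion cell genes, 0.00346 for Y-linked genes and 0.00196 for pigment epithelium genes, none past the threshold. Without each library in turn it lay between -0.0271 and -0.0172, between 0.00245 and 0.00433 and between 0.00146 and 0.00242, passing in some. The cause was not tested.

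With the replicate number as a block 6791 genes were called and 1140 at least 2-fold, and 6414 of the 6752 main calls remained. Deviations of same-numbered libraries correlated between -0.131 and 0.225, and not every library correlated best with its own number, so the numbers were not taken to pair the libraries. Knock-out replicate 6 has no wild-type library of the same number, so the block left it out of the genotype estimate. Under the block Pecam1 lost its call (-0.25) and Pias3 gained one (-0.17). Both log2 fold changes equalled those of the fit without knock-out replicate 6, so these changes are not particular to the block.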

Other observations

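The gene groups of the first paragraphs and the comparisons of ganglion and amacrine cell genes were chosen after the main results were seen; the splits of the libraries and the share of called genes near Nrl were set before. Members of 10 further groups were taken by symbol, when values of some members had already been seen, and tested with camera, adjusted over the 10; no group passed with an estimated correlation. Of 21 cholesterol synthesis genes 17 fell and 1 rose (median log2 fold change -0.49, adjusted p = 3.87e-07; adjusted p = 0.204 with an estimated correlation). Dhcr7 fell from 796 to 422 normalized counts (-0.92, SE 0.06) and Insig1 from 1297 to 714 (-0.86, SE 0.07). Of 12 complement genes and regulators 8 rose and 1 fell (median 1.03, adjusted p = 0.0011; adjusted p = 0.189 with an estimated correlation), with Cfi at 3.01 and Serping1 at 2.64. Of 26 chemokine and cytokine genes 15 rose and 5 fell (median 0.41, adjusted p = 0.014; 0.266 as adjusted p with an estimated correlation), among them Ccl5 (3.33), Lif (2.39) and Ccl9 (2.36). Of 27 cell death genes 15 rose and 4 fell (median 0.38, adjusted p = 0.014; 0.189 as adjusted p with an estimated correlation); Tnfrsf1a rose from 118 to 352 (1.57, SE 0.09) and Bcl2l11 fell by 1.18 (SE 0.07).

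Of 67 ribosomal protein genes 16 fell and 1 rose (median -0.15, adjusted p = 0.0164; 0.686 as adjusted p with an estimated correlation). The other groups were not past the threshold, namely synaptic vesicle and release genes (adjusted p = 0.0637), heat shock proteins (0.0741), the mitochondrial respiratory chain (0.151), the cell cycle (0.65) and extracellular matrix (0.809). Single members of these moved strongly. The type IV collagen genes Col4a3 (-3.53, SE 0.12) and Col4a4 (-2.91, SE 0.16) fell while Col4a5 rose (1.65, SE 0.14), and the matrix gene Tnc rose (1.85, SE 0.09). The near-identical heat shock genes Hspa1a (-1.96, SE 0.09) and Hspa1b (-2.05, SE 0.11) fell while Hsph1 rose from 1627 to 3866, and Bub1b rose from 507 to 1656 (1.71, SE 0.09). Among 104 families of genes that share a symbol stem, scanned in the same way after the results were seen, only the Parp genes passed, with 9 of 12 higher (median 0.57, adjusted p = 0.00997), and their adjusted p was 0.989 with an estimated correlation.

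Whether the genotype difference could arise by chance was tested by redrawing the groups. Of 100 splits of the 11 libraries into 5 and 6, the real one included, 1 called as many genes as the real split, the real one itself. A random split of these libraries is thus unlikely to call as many, although only 100 of the 462 splits were drawn. The splits cannot tell genotype from anything else that differs between the same groups. The real split called 6752 genes, the highest other split 4614 and the median of the others 0. At least 2-fold the values were 1133 and 894. The 4 other splits that called more than 1 gene put 5 knock-out libraries against the rest, so they follow genotype too.

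Some reads of rod genes remained in the knock-out libraries. Relative to wild type, Gnat1 stood at 0.0655% (counting interval 0.0620 to 0.0691), Cnga1 at 0.0538% (0.0413 to 0.0688) and Nr2e3 at 0.0502% (0.0339 to 0.0717). Nrl stood at 0.1398%, Slc24a1 at 0.385% and Kcnj14 at 0.398%. The source of these reads is not weighed here, so they do not by themselves show that knock-out retina expressed these genes.

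Ganglion and amacrine cell genes were lower as lists with the preset correlation, but not with an estimated one (adjusted p = 0.461 and 0.207), and bipolar and horizontal cell genes were not. Scaling of the libraries, which cancels within a library but for the added 1, is argued against as the cause of a gap between cell types, since the mean log2 level of ganglion and amacrine genes minus that of bipolar genes went from -0.247 ± 0.161 (SD, n = 5) to -0.790 ± 0.153 (SD, n = 6), a difference of -0.543 (exact permutation p = 0.00216, the smallest possible). How far ganglion and amacrine genes fell by themselves depends on scaling (medians of -0.22 and -0.18 with the library total). A larger photoreceptor share that dilutes every other cell type alike would leave no gap between these cell types. The difference was -0.628 against Müller glia genes (exact permutation p = 0.00216), some of which rise in glial reaction. Against horizontal cell genes it was -0.278 (exact permutation p = 0.026, adjusted 0.0312). These comparisons were chosen with the lists' directions known, so their p-values add no support. The shares of reads of the listed photoreceptor genes moved both ways. These genes are only a part of photoreceptor RNA and themselves changed with genotype, so they do not settle whether the photoreceptor share grew. Rod phototransduction genes fell from 8.79% to 0.561% of reads and shared genes from 5.20% to 3.54%. Cone phototransduction genes rose from 0.167% to 1.66%, other cone-enriched genes from 0.067% to 0.329% and synapse genes from 0.997% to 1.10%. Fewer such cells, or less expression in each, may underlie the pattern as a hypothesis; neither was tested, and in DESeq2 both lists missed the threshold (-0.35 and -0.31).

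DNA of another mouse strain carried along with the targeted locus would raise the share of called genes near Nrl. Of the 40 tested genes nearest to it 13 were called, which is 32.5% with an exact interval of 18.6% to 49.1%, against 46.4% of all other tested genes. The reading written beforehand took this as evidence against such DNA. After the value was seen it was weakened, because the share elsewhere lies inside the interval and a small excess cannot be told apart from none. The number of 40 was set beforehand, and of the other sizes computed the nearest 10 gave 40%, 20 gave 40%, 80 gave 35% and 160 gave 46.9%. Single neighbours such as Cmtm5 (1.61), Irf9 (303 to 729 normalized counts) and, chosen after its value was seen, Ppp1r3e (-1.54) stay open.

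P2ry12, Tmem119 and Cx3cr1, known from resting microglia, rose by 0.91, 1.37 and 1.31, against a median of 2.25 of the microglia list. These genes were chosen after their values were seen, after a larger set had been tried. No test of them is therefore given, and the cause of the difference stays open.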
